A study of Homo sapiens with 9 samples.

How the data were processed

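The samples were 9 RNA libraries of EGI-1 cells, an established human cholangiocarcinoma (bile duct cancer) line carrying a doxycycline-inducible short hairpin RNA. There were 3 libraries of a control hairpin (GFPsh) and 3 of each of 2 hairpins against FOSL1 (FOSL1sh3 and FOSL1sh10). Per the labels, doxycycline was given at 2 ug per ml for 4 days, and RNA was harvested after a further 24 hours from seeding. Groups and replicate numbers came from the sample titles. The labels do not state that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

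The authors deposited 1 table of raw counts per library, whole numbers of reads per gene that had not been normalized. Per the labels, libraries were made by a low-input protocol (MARS-seq). As background, that protocol tags transcripts near their 3' ends and marks molecules with identifiers. Per the labels, only RNA with a quality number (RQI) above the authors' minimum was used. Per the submitters' processing notes, reads were checked with FastQC 0.11.5 and aligned to hg38 with STAR 2.5.3a, and edgeR and limma were also named. Per the file headers, counts were made with featureCounts 1.6.0 over exons of each gene with GENCODE release 28, and no option for strand, multi-mapping reads or duplicates was set. Counts are therefore unstranded by the command shown. Reads of antisense or overlapping genes cannot be told apart, which makes CDC20-DT uncertain, and THBS1-IT1 is uncertain because it lies in an intron of THBS1 on the same strand. Whether molecular identifiers were used to collapse reads is not given in the sources used here, so the floor of 3 counts covers counting error only. Near-identical gene copies can share or lose reads, and values of SAA1, SAA2, KRT6B, RPL7, other ribosomal protein genes, HLA-DRB1, ALPG, KRTAP2-3 and IFITM2 are uncertain for that reason.

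Each file held 58381 genes, of which 57754 matched a current symbol by stable identifier and 58261 were found in GENCODE release 29, which was used for gene types, former symbols and 3' UTRs. Coordinates are those of hg38 as the files give them, from the first to the last exon base of a gene, counted from 1. A count in at least 1 library was found for 27513 genes. Library totals ranged from 6893026 to 10604251 counts. At these depths 3 counts, the upper limit that a count of 0 allows, correspond to 0.283 to 0.435 CPM, the count scaled to a common library total.

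Counts were tested with edgeR 4.0.16 (R 4.3.3): default expression filter (minimum count 10, minimum total 15), TMM scaling, and the quasi-likelihood F test in 1 fit over all 9 libraries with the group as the only term. This left 12814 genes. The comparisons were FOSL1sh3 against GFPsh, FOSL1sh10 against GFPsh, the mean of both hairpins against GFPsh, and FOSL1sh3 against FOSL1sh10. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors (SE) were computed as the size of the log2 fold change over the square root of the F statistic, and CPM values are scaled by TMM and given as mean ± SD. The common biological coefficient of variation was 16.4%. Genes called with both hairpins in the same direction were set against 50 simulations of unchanged groups sharing the same controls and against the overlap of independent lists.

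The 27 gene lists were AP-1 family, cholesterol synthesis, fatty acid synthesis, mitosis, DNA replication, MAPK output, ERBB and MET ligands and receptors, matrix proteolysis, mesenchymal genes, epithelial junctions, biliary markers, integrins and laminins, inflammatory mediators, interferon response, hypoxia and glycolysis, ER stress and amino acid response, p53 targets, YAP and TGF-beta targets, keratinocyte and squamous genes, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes, nuclear long RNAs, heat shock and immediate early genes, and markers of leukocytes, of fibroblasts and endothelium, and of hepatocytes. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Members were also counted with p-values adjusted over the list alone. Lists with 1 tested member had no list test.

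Named genes followed a rule. FOSL1 came first, then HMGCS1 and AURKA, which were named from knowledge of the study and had probably been chosen on these libraries. Next were the 12 higher and 12 lower genes with the largest mean change among those called with both hairpins, with a symbol, a mean of at least 30 counts and all hairpin libraries on one side of all controls. For each hairpin the 5 higher and 5 lower genes with the largest change were taken, and for the hairpins against each other the 8 higher and 8 lower, with the same count minimum. From each list up to 4 members with the smallest p in the mean contrast were taken, giving 139 distinct genes, of which 1 is not reported here. Groups, tests, lists, this rule and all alternatives other than those named below as later additions were fixed before the data were examined. The cholesterol synthesis and mitosis lists hold HMGCS1 and AURKA, so their choice may also reflect knowledge of the study.

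Alternatives were DESeq2-type median-of-ratios factors, library totals alone, no low-count filter, a stricter filter of 30 counts on average, DESeq2 1.42.0, limma-voom, the replicate number as a block, only the groups compared, an absolute log2 fold change of at least 1, and each library left out in turn. Removal of each library's trend on GC content and exon length as an offset, and leaving out 85 ribosomal protein genes, were chosen after seeing the data. Words of 7 bases in 3' UTRs of at least 50 bases (11062 genes) were tested for association with fold changes, with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A UTR was taken to hold Alu sequence where it shared 5 words of 10 bases with a consensus written down from general knowledge, so that this filter is approximate. Figures were drawn with matplotlib 3.10.9. The sequences of the hairpins are not given in the sources used here.

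The gene test was tested on simulated data for the FOSL1sh3 comparison over 12814 genes. It recovered 7.46% of planted changes of 0.5 on the log2 scale, 56.7% of changes of 1 and 89.4% of changes of 2, with 5 false calls among 12584 unchanged genes. Changes near 0.5 were thus mostly missed in the simulation. It gave 108 calls in all, against 1392 in the real comparison. With fewer calls the adjusted p limit is stricter, so recovery in the real data may be higher. In the same simulation camera called a planted list of 30 genes at -0.4 and did not call a random list. Genes were drawn independently there, so correlation among list members was not tested. The word search, tested on shuffled fold changes of the FOSL1sh10 comparison over 11062 genes, ranked a planted effect of -0.2 as number 1. Smaller effects, such as those reported below, were not planted. Shuffling also removes any link of fold changes with UTR length or composition, so the test does not cover words tied to these.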

Results

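Gene expression was measured in EGI-1 cells after induction of a hairpin against FOSL1, which encodes the AP-1 transcription factor FRA-1, or of a control hairpin. Each of the groups GFPsh, FOSL1sh3 and FOSL1sh10 had 3 libraries. Total counts were 7259635, 9015680 and 9211445 for GFPsh replicates 1, 2 and 3, 10604251, 7226334 and 8225037 for FOSL1sh3, and 6893026, 8060471 and 9139511 for FOSL1sh10. The groups therefore overlapped in depth. Ribosomal protein genes took 25.2% ± 0.766 of counts in GFPsh, 27.1% ± 0.237 in FOSL1sh3 and 21.9% ± 1.91 in FOSL1sh10 (SD, n = 3 each). Mitochondrially encoded genes took 2.60% ± 0.240, 2.72% ± 0.735 and 2.37% ± 0.298. In a principal component analysis the first component (30.1% of variance) placed the FOSL1sh3 libraries between 18.5 and 47.3 and the FOSL1sh10 libraries between -26.9 and -16.8, with GFPsh between -16.3 and -8.77. The second component (20.6%) held GFPsh at 21.5 to 29.2, FOSL1sh3 at -11.3 to 1.52 and FOSL1sh10 at -24.0 to -20.5.

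The targeted gene was examined first. FOSL1 (chromosome 11, 65892049 to 65900573, minus strand, hg38) was at 302, 256 and 182 CPM in the GFPsh libraries, at 72.1, 70.1 and 44.8 CPM with FOSL1sh3, and at 70.7, 57.0 and 65.7 CPM with FOSL1sh10. The mean fell from 247 ± 60.9 CPM to 62.3 ± 15.2 and 64.5 ± 6.95 CPM (SD, n = 3 each), which is 25.3% and 26.1% of the control. The log2 fold changes were -1.98 (SE 0.198, adjusted p = 1.2e-05) and -1.94 (SE 0.197, adjusted p = 1.03e-05), with all 6 hairpin libraries below all 3 controls. Between the hairpins FOSL1 differed by -0.05 (SE 0.195, adjusted p = 0.9), less than the spread between replicates.

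**Figure D1:**
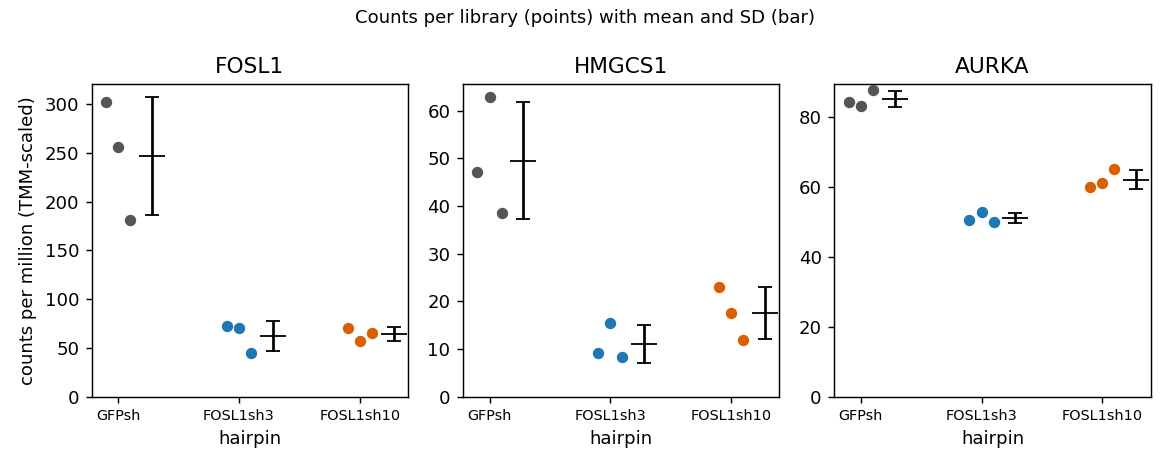
TMM-scaled CPM of FOSL1, HMGCS1 and AURKA in each library (points, n = 3 per hairpin), with the mean and SD of each group as a bar. All FOSL1 hairpin libraries lie below all GFPsh libraries for the 3 genes, with FOSL1 at 25.3% and 26.1% of the control mean.

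HMGCS1, the cytosolic HMG-CoA synthase of the mevalonate pathway, and AURKA, the mitotic kinase Aurora A, were followed up by the study as far as is known. They were probably chosen on these libraries and are not independent evidence. HMGCS1 (chromosome 5, 43289395 to 43313512) fell from 49.6 ± 12.3 CPM to 11.01 ± 3.94 with FOSL1sh3 and 17.6 ± 5.53 with FOSL1sh10 (SD, n = 3), log2 fold changes of -2.18 (SE 0.259, adjusted p = 7.38e-05) and -1.51 (SE 0.249, adjusted p = 0.00101). AURKA (chromosome 20, 56369389 to 56392337) fell from 85.2 ± 2.30 CPM to 51.2 ± 1.43 with FOSL1sh3, a log2 fold change of -0.74 (SE 0.126, adjusted p = 0.00164). With FOSL1sh10 it was at 62.2 ± 2.78 CPM, a log2 fold change of -0.45 (SE 0.125, adjusted p = 0.0398). That last call ended with library totals alone (adjusted p = 0.132) and with no low-count filter (0.1). It also ended without any 1 of the 3 GFPsh or 3 FOSL1sh10 libraries (0.0937 to 0.151).

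FOSL1sh3 against GFPsh asked which transcripts change when FOSL1 is reduced by the first hairpin. ITPK1, an inositol phosphate kinase, rose from 46.5 ± 4.06 to 160.4 ± 15.3 CPM (log2 fold change 1.79, SE 0.138). BEST2, a bestrophin ion channel, rose by 2.06 (SE 0.242), and the gel-forming mucin MUC5AC rose by 1.88 (SE 0.263). FOS, the AP-1 subunit, rose by 1.91 (SE 0.294) and ADAMTSL5 by 1.81 (SE 0.327). MTOR, the growth-control kinase, fell from 46.3 ± 8.26 to 12.4 ± 3.11 CPM (log2 fold change -1.91, SE 0.190). CCNG1 (cyclin G1) changed by -2.14 (SE 0.323) and TM4SF18 by -2.73 (SE 0.501), beside FOSL1 and HMGCS1. ITGB4 and ITGA3, laminin-binding integrin chains, rose by 1.45 and 0.80. The AP-1 gene JUNB rose by 1.15. The cell cycle inhibitor CDKN1A changed by -1.07 and the stress gene GADD45A by -0.96. The matrix protein gene TNC changed by -1.46 and VIM, vimentin, by -1.74. Adjusted p-values of these 7 genes ran from 8.28e-06 to 0.00685. In all 1392 genes were called, 668 higher and 724 lower, and 389 of them changed by at least 1 on the log2 scale. An unadjusted p under 0.05 was reached by 3447 genes, against 641 from chance. With library totals alone 34.0% of calls were higher, against 48.0%, and the median of all genes lay at -0.06. The count fell to 599, 895 and 747 without GFPsh replicate 1, 2 or 3 and to 756 without FOSL1sh3 replicate 3. It was 893 once a trend on GC content and length, added after seeing the data, was removed, and 49.8% of the 1392 were still called.

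Cholesterol synthesis genes fell together with FOSL1sh3. Of 25 members tested 11 fell (13 adjusted over the list alone), with a median log2 fold change of -0.54 (camera adjusted p = 2.58e-11, 0.0168 with an estimated correlation). Beside HMGCS1, INSIG1, which holds the SREBP system in the endoplasmic reticulum, changed by -1.48 (SE 0.184), the sterol oxidase MSMO1 by -0.94 (SE 0.141) and the isomerase IDI1 by -0.95 (SE 0.155). Fatty acid synthesis followed with 5 of 13 lower (6 adjusted over the list alone, adjusted p = 0.000597, 0.0354 with an estimated correlation), among them the desaturase SCD at -0.94 (SE 0.138) and the elongase ELOVL6 at -0.93 (SE 0.166). Of 32 mitosis genes 11 fell (17 adjusted over the list alone), with a median of -0.40 (adjusted p = 4.86e-10, 0.0188 with an estimated correlation). Cyclin B1, CCNB1, changed by -0.90 (SE 0.157) and the centromeric histone CENPA by -0.74 (SE 0.142). DNA replication had 6 of 31 lower (7 adjusted over the list alone, adjusted p = 0.000634, 0.0354 with an estimated correlation), led by the polymerase subunit POLE2 at -1.53 (SE 0.248). Among keratinocyte and squamous genes 4 of 15 rose and 2 fell (7 and 2 adjusted over the list alone), adjusted p = 0.0315. That call was lost at adjusted p = 0.276 with an estimated correlation. It was also lost without GFPsh replicate 2 (0.111) or 3 (0.0622) and with the GC content trend removed (0.209). Ribosomal proteins as a list were higher, median 0.17 (adjusted p = 0.0472, and adjusted p = 0.579 with an estimated correlation), with none of 32 members called. That list lost its call without GFPsh replicate 1, 2 or 3 or FOSL1sh3 replicate 1 (0.0501 to 0.193), with library totals alone (0.0589) and with the GC content trend removed (0.0691).

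FOSL1sh10 against GFPsh asked the same of the second hairpin. SAA2 and SAA1, the serum amyloid A acute-phase genes, rose from 8.77 ± 1.72 to 95.8 ± 4.90 CPM and from 159 ± 9.99 to 984 ± 16.6 CPM (log2 fold changes 3.44, SE 0.190, and 2.63, SE 0.153). ATP6V1C2, a proton pump subunit, rose by 3.06 (SE 0.370), the cytokine IL6 by 3.01 (SE 0.348) and the pentraxin PTX3 by 2.91 (SE 0.312). THBS1-IT1, which lies in an intron of THBS1 on the same strand, so that its reads may belong to THBS1, rose by 2.69 (SE 0.362). Beside FOSL1, RGS2, a regulator of G protein signalling, changed by -1.84 (SE 0.293), the aldehyde dehydrogenase ALDH3A1 by -1.91 (SE 0.301), PARP16 by -1.78 (SE 0.341) and the interferon-induced IFI44 by -2.05 (SE 0.491, adjusted p = 0.0183). CD74, the invariant chain of class II antigen presentation, rose from 30.3 ± 3.10 to 142 ± 21.2 CPM (log2 fold change 2.22, SE 0.160). In all 676 genes were called, 401 higher and 275 lower, 286 of them by at least 1 on the log2 scale, and 2488 had an unadjusted p under 0.05 against 641 from chance. With library totals alone 77.4% of calls were higher, against 59.3%, and the median of all genes lay at 0.11. The count was 1124 with only the GFPsh and FOSL1sh10 libraries in the fit. It was 397, 416 and 415 without GFPsh replicate 1, 2 or 3, and 422, 347 and 373 without FOSL1sh10 replicate 1, 2 or 3. The call of IFI44 ended without GFPsh replicate 1 (0.0865) or FOSL1sh10 replicate 2 (0.0672) or 3 (0.0955).

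Inflammatory mediators were the list with the smallest p with FOSL1sh10 at the preset correlation. Of 19 tested 16 rose (19 adjusted over the list alone), with a median of 1.15 (camera adjusted p = 9.53e-29, 0.00303 with an estimated correlation). Beside IL6, the macrophage growth factor CSF1 rose by 1.86 (SE 0.258) and the NF-kB subunit RELB by 1.09 (SE 0.165). The chemokine CCL20 rose by 1.68 (SE 0.423, adjusted p = 0.0242), a call that ended without FOSL1sh10 replicate 1 or 2 or any 1 control (0.0555 to 0.112). Interferon response genes rose in 13 of 26 cases and fell in 1, IFI44 (18 and 1 adjusted over the list alone), with a median of 0.75 (adjusted p = 1.8e-12, 0.00303 with an estimated correlation). ISG15 rose by 0.99 (SE 0.159), IFI27 by 1.01 (SE 0.161) and MX1 by 0.84 (SE 0.162). Keratinocyte and squamous genes rose in 5 of 15 cases and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 8.3e-09, 0.0104 with an estimated correlation), with the basal keratin KRT5 from 120.4 ± 9.15 to 422 ± 33.0 CPM (log2 fold change 1.81, SE 0.133) and KRT17 at 0.79 (SE 0.152). Matrix proteolysis rose in 5 of 16 (6 adjusted over the list alone, adjusted p = 0.000101, 0.0146 with an estimated correlation), including the plasminogen activators PLAT at 1.20 (SE 0.133) and PLAU at 1.17 (SE 0.138) and the receptor PLAUR at 0.73 (SE 0.138).

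Cholesterol synthesis fell with FOSL1sh10 in 8 of 25 genes (13 adjusted over the list alone), median -0.46 (adjusted p = 9.1e-09, 0.0104 with an estimated correlation), with MSMO1 at -0.73 (SE 0.140). INSIG1 was at -0.69 (adjusted p = 0.0264) and IDI1 at -0.56 (adjusted p = 0.0381). Both lost their calls without FOSL1sh10 replicate 1, 2 or 3 or GFPsh replicate 2 or 3, and IDI1 also without GFPsh replicate 1 (0.0554 to 0.187). Both also lost them with library totals alone (0.0597 and 0.0759). Mitosis genes fell in 10 of 32 cases (23 adjusted over the list alone), median -0.46 (adjusted p = 9.33e-13, 0.0067 with an estimated correlation), with the topoisomerase TOP2A from 68.8 ± 5.99 to 34.0 ± 1.46 CPM (log2 fold change -1.02, SE 0.150). DNA replication fell in 4 of 31 (5 adjusted over the list alone, adjusted p = 4.39e-05, 0.0104 with an estimated correlation) and fatty acid synthesis in 3 of 13 (7 adjusted over the list alone, adjusted p = 0.000332, 0.0193 with an estimated correlation), the latter with the desaturase FADS1 at -1.07 (SE 0.215). Of 13 mitochondrially encoded genes 6 fell (6 adjusted over the list alone, adjusted p = 1.02e-06, 0.0146 with an estimated correlation), including MT-ND5 from 988 ± 98.2 to 464 ± 34.3 CPM (-1.09, SE 0.137), MT-ND4L (-1.32, SE 0.197) and MT-ND3 (-1.03, SE 0.175), subunits of respiratory complex I. Further lists passed at the preset correlation and were lost with an estimated one. Ribosomal proteins were lower with a median of -0.22 and none of 32 members called (adjusted p = 9.12e-05, and adjusted p = 0.152 with an estimated correlation). The AP-1 family was higher with 0 of 12 called and 4 adjusted over the list alone (0.00935, and adjusted p = 0.139 with an estimated correlation). Mesenchymal genes had 1 of 12 higher and 2 adjusted over the list alone (0.0203, and adjusted p = 0.0815 with an estimated correlation). Epithelial junctions had 1 of 20 higher and 1 adjusted over the list alone (0.0387, and adjusted p = 0.152 with an estimated correlation). Leukocyte markers had 1 of 3 higher, and 2 higher and 1 lower adjusted over the list alone (0.000101, and adjusted p = 0.0626 with an estimated correlation). The gene higher among leukocyte markers was CD74, which epithelial cells can also express. Mesenchymal genes also lost the call without GFPsh replicate 2 (0.0534), and epithelial junctions without GFPsh replicate 3 (0.119) or FOSL1sh10 replicate 3 (0.147) and with the GC content trend removed (0.0905).

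What both hairpins had in common was examined next, since their target is the same. The higher genes with the largest mean change were SAA2 (1.31 with FOSL1sh3 and 3.44 with FOSL1sh10), ATP6V1C2 (1.6 and 3.06), the keratin KRT6B (1.43 and 2.53), the adhesion molecule L1CAM (1.71 and 1.56) and ITPK1 (1.79 and 1.48). They also included SAA1 (0.60 and 2.63), the nicotinamide methyltransferase NNMT (0.95 and 2.27), the calmodulin-like CALML5 (1.66 and 1.52), ADAMTSL5 (1.81 and 1.29). The others were the selenoprotein SELENOM (1.36 and 1.54), the leukotriene synthase LTC4S (1.21 and 1.67) and CDC20-DT (1.45 and 1.16). The lower genes were FOSL1, HMGCS1, RGS2 (-1.82 and -1.84), the long noncoding RNA LINC00707 (-1.74 and -1.67), the homeobox gene BARX2 (-1.85 and -1.39). Also lower were the interleukin 1 receptor antagonist IL1RN (-1.72 and -1.47), TMEM158 (-1.81 and -0.90), POLE2 (-1.53 and -1.01). The others were the peptidase DPP4 (-1.54 and -0.91), MT-ND4L (-1.12 and -1.32), the carcinoembryonic antigen family member CEACAM6 (-1.27 and -1.04) and C16orf87 (-0.95 and -1.23). IL1RN went from 66.4 ± 6.08 CPM in GFPsh to 20.2 ± 2.43 and 24.0 ± 0.776 CPM, and L1CAM from 6.69 ± 0.890 to 22.0 ± 4.77 and 19.8 ± 2.59 CPM (SD, n = 3 each). All 6 hairpin libraries lay on one side of all 3 controls for these 24 genes, which the rule for naming them required. Some calls rested on single libraries. With FOSL1sh3, leaving out 1 library ended the calls of ATP6V1C2 (FOSL1sh3 or GFPsh replicate 3, 0.0633 and 0.0765), LTC4S (GFPsh or FOSL1sh3 replicate 2 or 3, 0.0655 to 0.123) and SAA1 (GFPsh replicate 1 or 3 or FOSL1sh3 replicate 3, 0.0518 to 0.0613). With FOSL1sh10 it ended those of ADAMTSL5 (GFPsh replicate 1 or 2, FOSL1sh10 replicate 2 or 3, 0.054 to 0.156), CDC20-DT (any control or FOSL1sh10 replicate 2 or 3, 0.0553 to 0.15). It also ended the calls of TMEM158 (GFPsh or FOSL1sh10 replicate 1 or 3, 0.0795 to 0.108), POLE2 (GFPsh replicate 1 or 3, FOSL1sh10 replicate 1 or 2, 0.0669 to 0.0875) and DPP4 (GFPsh replicate 2 or 3 or any FOSL1sh10 library, 0.0542 to 0.235). DPP4 also lost it with library totals alone (0.0655), and removal of the GC content trend ended the calls of LTC4S (0.125) and SAA1 (0.0671) with FOSL1sh3 and of ADAMTSL5 (0.0516) with FOSL1sh10. LTC4S with FOSL1sh3 was also lost with only the groups compared (0.061).

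In all 199 genes were called with both hairpins in the same direction, 131 higher and 68 lower, and 19 in opposite directions. Independent lists of these lengths would share 36.4 genes in the same direction (20.9 higher, 15.5 lower) and 37.0 in opposite directions. In 50 simulations of unchanged groups against the same controls the overlap was 0, but groups without changed genes yield hardly any calls. At an unadjusted p under 0.05 in both, 882 genes shared a direction against a simulated 124 (103 to 142). Opposite directions were found for 132 against 0.58. The simulations do not cover unrelated changes in 2 groups that share a reference. Across genes, which are not independent replicates, the log2 fold changes of the hairpins had a Pearson correlation of 0.396 (Spearman 0.367), below the 0.499 (0.482 to 0.519) that shared controls alone gave. The covariance was 0.0937 against a simulated 0.0428, a difference of 0.051. The 3 control libraries were not split, since 1 part would hold a single library, so part of the excess may come from them. The count of 199 was 100, 118 and 99 without GFPsh replicate 1, 2 or 3 and 129, 123 and 115 without FOSL1sh10 replicate 1, 2 or 3, and 54 genes also changed by at least 1 with both hairpins.

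In the mean of both hairpins against GFPsh 797 genes were called, 416 higher and 381 lower, 185 of them by at least 1, with 2753 at an unadjusted p under 0.05 against 641 from chance. Mitosis fell in 14 of 32 genes (24 adjusted over the list alone, median -0.51, camera adjusted p = 4.75e-16, 0.00506 with an estimated correlation) and cholesterol synthesis in 13 of 25 (17 adjusted over the list alone, median -0.43, adjusted p = 8.63e-15, 0.00506 with an estimated correlation). HMGCS1 and AURKA are members of these lists, which may therefore not be independent of the study's choice either. DNA replication had 4 of 31 lower (7 adjusted over the list alone, adjusted p = 3.6e-06), fatty acid synthesis 3 of 13 (6, adjusted p = 9.18e-06) and mitochondrially encoded genes 5 of 13 (6, adjusted p = 2.29e-05), and each held with an estimated correlation (0.00854, 0.0125 and 0.0286). Keratinocyte and squamous genes had 6 of 15 higher and 1 lower (7 and 2 adjusted over the list alone, adjusted p = 3.39e-06), the interferon response 8 of 26 higher (13 higher and 1 lower, adjusted p = 1.64e-06) and inflammatory mediators 4 of 19 (13, adjusted p = 5.04e-08), again held with an estimated correlation (0.0257, 0.00854 and 0.0274). Matrix proteolysis had 4 of 16 higher (5 higher and 1 lower adjusted over the list alone, 0.0126, and adjusted p = 0.0631 with an estimated correlation), a call also lost without GFPsh replicate 2 (0.0597). The AP-1 family had 2 of 12 higher (3 adjusted over the list alone, 0.0155, and adjusted p = 0.208 with an estimated correlation), a call also lost with the GC content trend removed (0.266). With FOSL1sh3 alone camera called neither the inflammatory mediators (0 higher, 3 lower, adjusted p = 0.742) nor the interferon response (0.171). Nor did it call mitochondrially encoded genes (0.069), matrix proteolysis (0.544) or the AP-1 family (0.171). The calls of these lists in the mean therefore do not show a change with both hairpins. The count of 797 was 316, 454 and 312 without GFPsh replicate 1, 2 or 3 and 529 and 524 without FOSL1sh10 replicate 1 or 3.

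**Figure D2:**
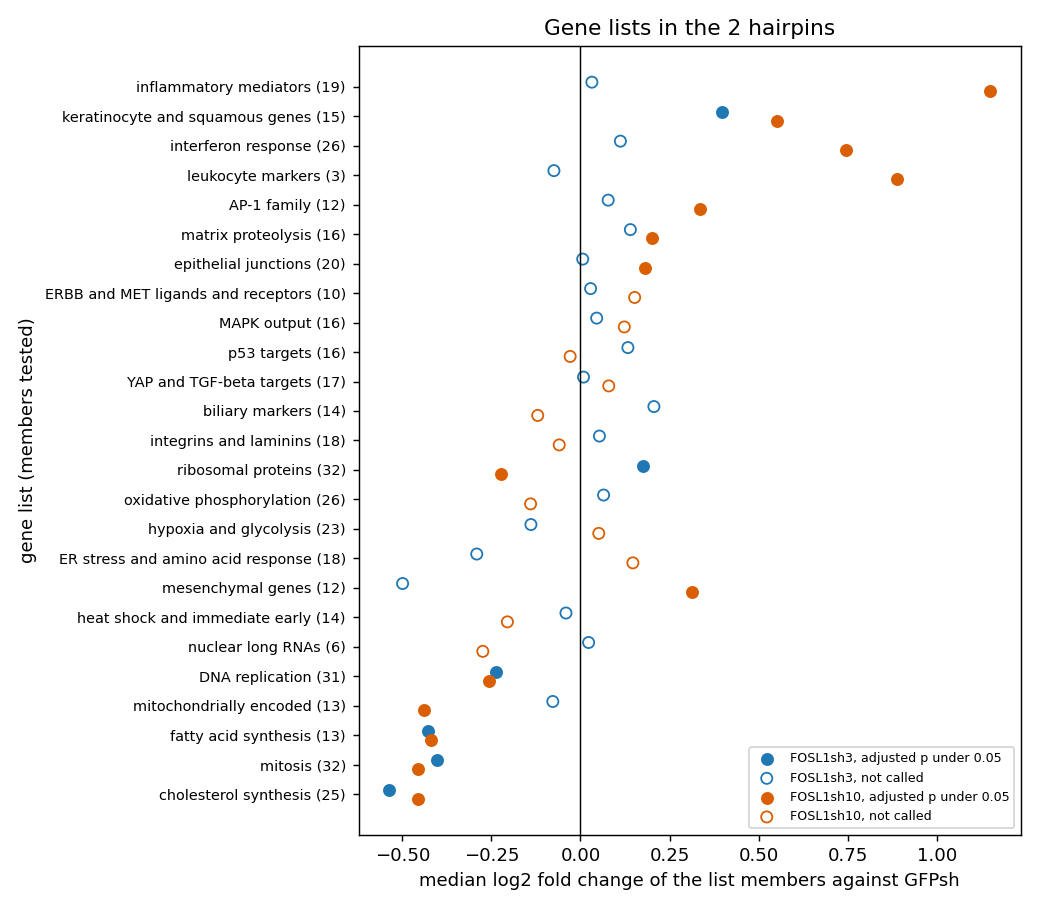
Median log2 fold change against GFPsh of the members of each gene list with FOSL1sh3 (blue) and FOSL1sh10 (orange), with filled points where camera gave an adjusted p under 0.05 at the preset correlation and the number of members tested in brackets. Cholesterol synthesis (-0.54 and -0.46) and mitosis (-0.40 and -0.46) lie on the left with both hairpins, and inflammatory mediators at 1.15 with FOSL1sh10 and 0.03 with FOSL1sh3.

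FOSL1sh3 against FOSL1sh10 asked where the hairpins part at FOSL1 levels whose difference lay within its error. Higher with FOSL1sh3 were PARP16 (2.85, SE 0.323), BEST2 (2.75, SE 0.255), MUC5AC (2.65, SE 0.281), the placental-type phosphatase ALPG (2.37, SE 0.243), DLK2 (2.16, SE 0.228) and the cortisol-inactivating HSD11B2 (2.06, SE 0.298). RPL7 (2.35, adjusted p = 0.0184) and TOP2B (2.08, adjusted p = 0.00885) were also named by the rule. RPL7 lost its call with DESeq2 (0.0704), limma-voom (0.0585) and without FOSL1sh3 replicate 1 or FOSL1sh10 replicate 2 or 3 (0.0662 to 0.208), and TOP2B with DESeq2 (0.0574) and without FOSL1sh3 replicate 1 (0.0568). Lower with FOSL1sh3 were HLA-DRB1 (-3.41, SE 0.376), TM4SF18 (-2.83, SE 0.499), the hexosamine enzyme GFPT2 (-2.75, SE 0.291), and IL6 (-2.73, SE 0.340). Also lower were PTX3 (-2.57, SE 0.304), the chemokine CXCL8 (-2.55, SE 0.406), SLC43A3 (-2.51, SE 0.266) and the keratin-associated KRTAP2-3 (-2.33, SE 0.195), and MTOR differed by -2.05 (SE 0.190). In all 1632 genes were called, 736 higher and 896 lower with FOSL1sh3, 526 of them by at least 1, with 3593 at an unadjusted p under 0.05 against 641 from chance. This difference test called 555 of the 1174 genes called with FOSL1sh3 but not with FOSL1sh10, 272 of the 458 called with FOSL1sh10 but not with FOSL1sh3, and 25 of the 199 called with both. With library totals alone 17.6% of calls were higher, against 45.1%, and the median of all genes lay at -0.17. The count was 1051 without FOSL1sh3 replicate 3 and 712 and 907 without FOSL1sh10 replicates 2 and 3.

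Inflammatory mediators differed most between the hairpins as a list, with 15 of 19 lower with FOSL1sh3 (16 adjusted over the list alone), a median of -1.57 (camera adjusted p = 4.77e-23, 0.0119 with an estimated correlation). Against GFPsh, none was called higher with FOSL1sh3 and 3 were lower, with a median of 0.03 (adjusted p = 0.742), a list test that pointed downward against the sign of its median. CXCL8 was 1 of the 3 (-1.66, SE 0.423, adjusted p = 0.0185), and that call ended without GFPsh replicate 1 or 3 or FOSL1sh3 replicate 3 (0.0695 to 0.0791) and with the GC content trend removed (0.0854). The interferon response was lower in 8 of 26 genes and higher in 1 (12 and 1 adjusted over the list alone, adjusted p = 3.47e-05, 0.0265 with an estimated correlation), and against GFPsh it had not been called with FOSL1sh3 (6 higher, 7 higher and 1 lower adjusted over the list alone, adjusted p = 0.171). ER stress and amino acid response genes were lower in 6 of 18 (7 adjusted over the list alone, adjusted p = 0.00033, 0.0391 with an estimated correlation), with the chaperone HSPA5 at -1.04 (SE 0.155). Ribosomal proteins were higher in 10 of 32 (21 adjusted over the list alone, 2.78e-08, and adjusted p = 0.128 with an estimated correlation), beside the shares of 27.1% and 21.9% of counts given above. The remaining lists called at the preset correlation were lost with an estimated one. Mesenchymal genes had 4 of 12 lower and 4 adjusted over the list alone (0.00242, and adjusted p = 0.0689 with an estimated correlation). Leukocyte markers had 1 of 3 lower and 1 adjusted over the list alone (0.00189, and adjusted p = 0.155 with an estimated correlation). Oxidative phosphorylation had 2 of 26 higher and 4 adjusted over the list alone (0.00617, and adjusted p = 0.318 with an estimated correlation). Integrins and laminins had 4 of 18 higher, and 5 higher and 1 lower adjusted over the list alone (0.0167, and adjusted p = 0.155 with an estimated correlation). Keratinocyte and squamous genes had 5 of 15 lower and 2 higher, and 6 and 3 adjusted over the list alone (0.0167, and adjusted p = 0.202 with an estimated correlation). Matrix proteolysis had 3 of 16 lower and 1 higher, and 6 and 1 adjusted over the list alone (0.0217, and adjusted p = 0.128 with an estimated correlation). Epithelial junctions had 4 of 20 lower, and 4 lower and 1 higher adjusted over the list alone (0.0485, and adjusted p = 0.223 with an estimated correlation). Mitochondrially encoded genes had 3 of 13 higher and 4 adjusted over the list alone (0.0485, and adjusted p = 0.224 with an estimated correlation). Library totals alone ended that last call too (0.0502), and leaving out ribosomal protein genes, added after seeing the data, that of epithelial junctions (0.0538). Single libraries ended the calls of epithelial junctions (FOSL1sh10 replicate 3, FOSL1sh3 replicate 1 or 3, 0.0654 to 0.148), integrins and laminins (FOSL1sh10 replicate 1, FOSL1sh3 replicate 2, 0.0605 and 0.0704). They also ended those of mitochondrially encoded genes (FOSL1sh10 replicate 3, FOSL1sh3 replicate 1 or 3, GFPsh replicate 3, 0.0543 to 0.107) and oxidative phosphorylation (FOSL1sh3 replicate 1, 0.0654). Mitosis (adjusted p = 0.979), DNA replication (0.979), cholesterol synthesis (0.148) and fatty acid synthesis (0.782) were not called between the hairpins, which does not show that they were alike. Of 13 fatty acid synthesis genes 2 were called higher and 3 lower with FOSL1sh3 than with FOSL1sh10, where 12.7% of all genes were called. Against GFPsh the elongase ELOVL6 was at -0.93 with FOSL1sh3 and -0.09 with FOSL1sh10, and the desaturase FADS1 at -0.05 and -1.07.

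**Figure D3:**
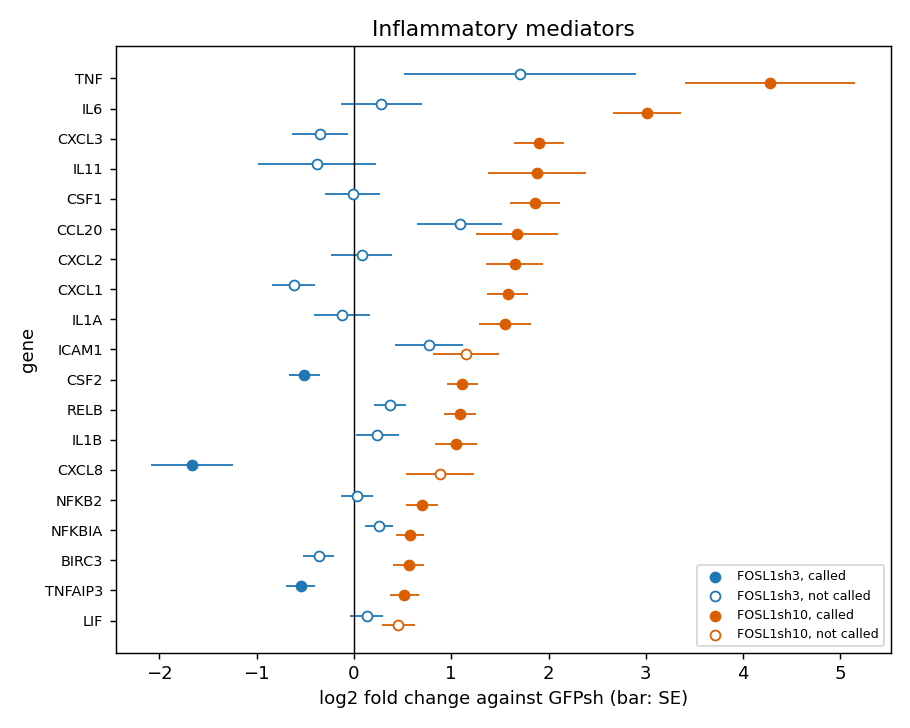
Log2 fold change against GFPsh (bars, SE) of the 19 inflammatory mediators tested, with FOSL1sh3 in blue and FOSL1sh10 in orange and filled points where the gene was called. With FOSL1sh10 16 were called higher, and with FOSL1sh3 none was called higher and 3 lower.

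No call in any of the 4 comparisons was made for MAPK output, ERBB and MET ligands and receptors, biliary markers, hypoxia and glycolysis, p53 targets, YAP and TGF-beta targets, nuclear long RNAs, or heat shock and immediate early genes. Adjusted p-values follow in the order FOSL1sh3, FOSL1sh10 and the hairpins against each other. They were 0.78, 0.668 and 0.979 for MAPK output (16 tested), 0.742, 0.47 and 0.903 for ERBB and MET (10), and 0.365, 0.91 and 0.441 for biliary markers (14). They were 0.418, 0.35 and 0.0741 for hypoxia and glycolysis (23), 0.706, 0.584 and 0.339 for p53 targets (16), and 0.885, 0.602 and 0.903 for YAP and TGF-beta targets (17). They were 0.651, 0.225 and 0.0904 for nuclear long RNAs (6) and 0.885, 0.598 and 0.881 for heat shock and immediate early genes (14). Single members were called. MUC1, a membrane mucin, rose by 0.88 (SE 0.146) and the carbonic anhydrase CA2 changed by -1.41 (SE 0.193) with FOSL1sh3, and with FOSL1sh10 the growth factor VEGFA rose by 0.94 (SE 0.169) and the small heat shock protein gene HSPB1 by 0.77 (SE 0.140). Markers of fibroblasts and endothelium and of hepatocytes had 1 tested member each, COL1A1 (0.58 and 0.79, not called) and SERPINA1 (0.56, not called, and 1.27, adjusted p = 0.00141).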

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

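The tests of the FOSL1 level between the hairpins, of Alu repeats and of leukocyte markers other than LCP1, and the fits without a GC content and length trend and without ribosomal protein genes, were chosen only after results had been seen.

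ALPG, GFPT2, KRTAP2-3 and PARP16 were the named genes called in opposite directions with the hairpins, each with a tested difference between them (edgeR, FOSL1sh3 against FOSL1sh10). ALPG was at 1.32 with FOSL1sh3 and -1.05 with FOSL1sh10, a difference of 2.37 (SE 0.243, adjusted p = 7.67e-06). PARP16 was at 1.07 and -1.78, a difference of 2.85 (SE 0.323, adjusted p = 1.97e-05). GFPT2 was at -1.03 and 1.72, a difference of -2.75 (SE 0.291, adjusted p = 1.03e-05). KRTAP2-3 was at -0.96 and 1.37, a difference of -2.33 (SE 0.195, adjusted p = 9.94e-07). Calls against GFPsh were less firm: that of ALPG with FOSL1sh10 ended without FOSL1sh10 replicate 1 or 2 or GFPsh replicate 3 (0.0706 to 0.104), and that of PARP16 with FOSL1sh3 without FOSL1sh3 replicate 1 or GFPsh replicate 1, 2 or 3 (0.0562 to 0.0713). That of GFPT2 with FOSL1sh3 ended with limma-voom (0.0828), with only the groups compared (0.0893), and without FOSL1sh10 replicate 3, FOSL1sh3 replicate 2 or 3 or GFPsh replicate 1 or 2 (0.059 to 0.142).

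The hairpins differed in 1632 genes while FOSL1 differed by -0.05 (SE 0.195), which argues against unequal knockdown of the FOSL1 transcript as the cause. The data hold no level of the FRA-1 protein, so unequal loss of the protein was not tested. Of 1631 such genes with a GC content, 74.8% were still called with each library's GC content and length trend removed, and 96.9% of the others without ribosomal protein genes, which argues against these as the whole cause. The 3' UTR word of 7 bases that went with the lowest levels with FOSL1sh10 against FOSL1sh3 was GTGCCAC (t = -7.557, Bonferroni limit 4.517; -6.371 without UTRs holding Alu sequence), which occurs in the FOSL1 3' UTR, as 10.4% of words occur in its transcripts. The 1605 of 11062 genes with this word had a fitted difference of -0.11 (SE 0.0145). Sites were this word, another word of 7 bases or a site of 8. Genes lower with FOSL1sh10 held a site in 43.4% of 244 cases against 23.2% of others (Fisher's exact test, adjusted p = 1.9e-11). For those not called with FOSL1sh3 it was 48.3% of 178, and for genes lower with both 29.3% of 58 (adjusted p = 3.79e-12 and 0.44). The word had been chosen on these libraries. PARP16 and C16orf87 held a site of 8, but ITPK1, which rose, held a word of 7. Seed-like off-target effects of FOSL1sh10 may add to its lower genes but stay a hypothesis, since its sequence is not known. For FOSL1sh3 the leading word TGGAAGC (t = -4.633) also occurs in FOSL1, but against GFPsh it missed the limit (t = -3.009) and GCAAGAA led (t = -4.569), which does not occur there, and without Alu-bearing UTRs no word went with lower levels past the limit, so seed effects of that hairpin stay open, as do biological differences between the cultures, which were not tested.

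With FOSL1sh10 16 of 19 inflammatory mediators rose, 14 of which also differed between the hairpins. Leukocytes in the cultures are argued against: CD74 rose from 30.3 to 142 CPM with PTPRC, CD3E and TYROBP at 0 CPM, and 12 leukocyte markers other than CD74 and LCP1 rose in sum by 2.38% of its rise, carried by CD14 (3.81 to 6.99 CPM, adjusted p = 0.0716, and 6.1 CPM with FOSL1sh3). The sum over 7 transcripts chosen before the result was seen, -21.2% of that rise, decides nothing, since it was carried by LCP1, at 81.2 CPM in the controls. A single deviating library is also argued against, since at least 11 of the 16 were still called without each FOSL1sh10 library in turn. Interferon induction by double-stranded RNA, as a hairpin could provoke, stays open, because 6 interferon-induced sensors and effectors had a median of 0.81, between the bound of 0.3 set for excluding it and the 1.15 of the mediators, and biological differences between the cultures were not tested.

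Mitosis and cholesterol synthesis genes were lower with both hairpins. A chance state of single control libraries is argued against, since all 3 controls scored above all 6 hairpin libraries for both lists, by at least 0.3363 on the log2 scale. That ordering has an exact permutation p of 0.0119 over 84 splits, the smallest they can give, and an adjusted p of 0.0744 over the lists. Both lists had been called lower on these same libraries, so the ordering is not independent evidence of a fall. Scaling is argued against, as the highest median over both lists, both hairpins and every scaling was -0.35. A state shared by all 3 control cultures cannot be told apart from an effect of FOSL1 loss, since the design has 1 control hairpin, so a biological effect of FOSL1 loss may account for it but remains a hypothesis.

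Other splits of the same libraries were fitted, for pairs of groups with only the 6 libraries concerned. For FOSL1sh3 against GFPsh the real split called 966 genes and the highest other 0, for FOSL1sh10 1124 and 0, and between the hairpins 1310 and 0, with 1 of 10 splits as large in each, which is too few for a share under 0.05. For the mean of both hairpins the 6 hairpin libraries were merged into 1 group of 6 against 3, a different fit from the one that called 797 genes with the hairpins as separate groups. In that merged fit the real split called 159 genes, and 3 of 84 splits called as many, a share under 0.05. These 3 each set 1 whole group against the rest, and splits that mixed groups called at most 3 genes. The share thus reflects that the libraries form 3 groups. It cannot tell an effect against the control from other differences between groups. The highest other, 1025, set the FOSL1sh3 libraries against the rest, and the FOSL1sh10 libraries against the rest gave 378, which points to a structure of the samples, namely their 3 groups. For genes called with both hairpins 2 of 100 groupings gave 199 or more, a share under 0.05. Of these, 1 was the real grouping and the other, 307, used the FOSL1sh10 libraries as the reference. A further grouping with that reference gave 83, FOSL1sh3 as the reference gave 164, and references that mixed groups gave 0. The count therefore cannot be told apart from the overlap that any whole group as the reference may give.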

How the results depend on the processing

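The fits without a GC content and length trend and without ribosomal protein genes were chosen only after the data had been seen. The log2 fold change of FOSL1 kept its direction and call under every alternative, from -2.17 to -1.80 with FOSL1sh3 and from -2.12 to -1.77 with FOSL1sh10 when 1 library was left out. Counts of calls moved by over 1.5 times without any 1 GFPsh or FOSL1sh10 library or FOSL1sh3 replicate 3, and under the settings named next. With only the groups compared FOSL1sh10 against GFPsh called 1124 genes, and with the trend removed FOSL1sh3 against GFPsh called 893. That trend took 19.3% of the variance of FOSL1sh3 replicate 3 and 14.3% of GFPsh replicate 3. With an absolute log2 fold change of at least 1, 389 genes remained for FOSL1sh3, 286 for FOSL1sh10, 185 for the mean of both, 526 between the hairpins and 54 for both hairpins, by the construction of that limit. An estimated correlation left 24 of 42 list calls. Leaving out 1 library gave 599 to 1803 genes for FOSL1sh3, 347 to 919 for FOSL1sh10, 312 to 1002 for the mean, 712 to 1920 between the hairpins and 99 to 219 for both hairpins. Apart from the fold change limit, the cause of these shifts was not tested. Of 303 calls of named genes 59 were lost under at least 1 setting, 90 without at least 1 library, and 212 held throughout; of 42 list calls these numbers were 18, 9 and 24. No call reversed. In the simulation 7.46% of planted changes of 0.5 were recovered, with fewer calls and so a stricter limit than in the real comparison. Replicate numbers did not pair the libraries over all groups (same-number correlations of deviations from -0.116 to 0.183, other numbers from -0.165 to 0.156). Between GFPsh and FOSL1sh3 alone, same-number correlations were 0.183, 0.0291 and 0.129, and those of other numbers -0.165 to 0.0333. Pairing of these groups therefore cannot be excluded. With the replicate block 1456 genes were called for FOSL1sh3, 695 for FOSL1sh10, 812 for the mean, 1673 between the hairpins and 213 for both hairpins, and AURKA with FOSL1sh10 had an adjusted p of 0.0569. The mean of both hairpins has no value with only the groups compared.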

Other observations

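The test of control hairpin seed matches was chosen only after results had been seen, and the genes of the next paragraph were chosen after their values were seen.

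Of 6 class II antigen presentation genes tested 5 rose with FOSL1sh10 and 0 with FOSL1sh3, and 5 differed between the hairpins (medians 2.08 and -0.69). HLA-DPA1 rose by 2.31 (SE 0.430, adjusted p = 0.00295), HLA-DMA by 0.97 (SE 0.216, adjusted p = 0.0116) and CD74 by 2.22, while their transactivator CIITA was at 1.17 and not called (adjusted p = 0.228). HLA-DRA was called narrowly (adjusted p = 0.0491) at a mean of 10.7 counts. Of 7 class I genes 4 rose with FOSL1sh10 and 2 with FOSL1sh3. HLA-B was at 0.94 (adjusted p = 0.000309) and 0.61 (adjusted p = 0.00925), and HLA-F rose with FOSL1sh10 by 0.72 and differed between the hairpins (adjusted p = 0.00406). Of 5 genes of class I antigen processing 1 rose with FOSL1sh10, the immunoproteasome subunit PSMB9 by 1.24 (SE 0.133, adjusted p = 1.8e-05), while TAP1, TAP2, PSMB8 and NLRC5 were not called (adjusted p = 0.0587 to 0.546). The 4 acute-phase genes picked here and found among those tested, SAA1, SAA2, LCN2 and C3, were all called higher with both hairpins. This says nothing of other such genes. CFB had also been picked but was not found by its symbol among the genes tested. LCN2, lipocalin 2, rose by 1.39 with FOSL1sh3 and 0.85 with FOSL1sh10, and C3, complement component C3, by 1.30 and 0.92. The SAA1 call with FOSL1sh3 ended without single libraries and with the GC content trend removed, as given above. Among mitochondrially encoded genes, the 7 complex I genes had medians of -0.73 with FOSL1sh3 (4 lower) and -1.03 with FOSL1sh10 (5 lower), and the 6 others 0.21 (0 lower) and 0.16 (1 lower).

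A hypothesis was that the control hairpin lowers genes by seed matches, which would make them appear higher with both FOSL1 hairpins. The word TGTTGTC in 3' UTRs went with higher levels with FOSL1sh3 (t = 7.464) and FOSL1sh10 (t = 8.446), past the limit of 4.517, with t = -0.902 between the hairpins, and it does not occur in FOSL1. Genes called higher with both held it in 17.07% of 123 cases against 13.4% of other genes (Fisher's exact test, p = 0.23, adjusted p = 0.46), an excess of 4.6 genes. Of genes called higher with FOSL1sh10 and not called with FOSL1sh3, 22.2% of 225 held it against 13.2% (adjusted p = 0.000908). Of those higher with FOSL1sh3 and not called with FOSL1sh10, 13.7% of 474 held it against 13.4% (adjusted p = 1.0). The word had been chosen on the same fold changes. Seed effects of the control hairpin may add small shifts to both comparisons against GFPsh, but whether they account for genes called with both cannot be told apart here, since the sequence of the control hairpin is not known and it is the only control.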
